A study of Homo sapiens with 15 samples.

How the data were processed

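Detroit is a human cell line that was grown as an orthotopic xenograft in NSG mice, which lack a working adaptive immune system. From each of 5 biological replicates, numbered 1, 2, 3, 4 and 6, the submitters sorted 3 populations by flow cytometry, which their labels call DID+, DID- and CD44DIM. Each population and replicate gave 1 array, so 15 arrays were analysed, 5 per population. Per the labels' protocols, total RNA of the sorted cells was amplified by whole-transcriptome amplification, and the resulting cDNA was labelled with Cy3 and hybridised to 1-colour Agilent arrays.

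The scanner files hold the fluorescence intensity of 62976 spots per array, which were read with Agilent Feature Extraction 10.7.3.1, per the file headers. The processed intensity in the deposited scanner files had a fitted spatial background surface subtracted and a multiplicative trend divided out by that software, with surrogate values for dim spots, per the file headers and columns, and was not yet normalised between arrays. Probe positions in the files are on build hg19 (GRCh37), per the file headers. A series table deposited by the authors holds log2 values for the same arrays. Its processing steps are not given in the sources used here beyond the name limma, per the submitters' processing notes. In each of the 15 arrays the table correlated with the array's own scanner values, with r from 0.952 to 0.987 across probes. It correlated at 0.999 or above with normexp background correction followed by quantile normalisation of the same scanner files, and column medians lay between 7.64 and 7.69. Its log2 scale and the direction of its values were thereby settled, and no centring of genes was seen. All columns of the table were matched to a sample.

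The main values were log2 of the processed intensity minus each array's 75th percentile. The 4259 control spots were left out, and spots flagged as outliers were dropped before spots of 1 probe were averaged. This removed 80 probes with no value on at least 1 array. A probe was taken as well above background on an array when a share of at least 0.5 of its spots carried the scanner's flag for it, and probes above background on at least 5 of the 15 arrays were tested. Of 50599 probe names, 31411 were named through a RefSeq gene table of another assembly (GRCh38.p14), used for names only. The remaining 19188 kept the name in the files. For a gene with several probes, the probe with the highest mean was tested, which left 32013 genes. Of these, 19658 were named through the gene table. The rest kept the name in the files, and each such name is counted as a gene. No probe was saturated. XIST and Y-linked genes were left out of the tables.

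Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 on all 15 arrays, with the replicate number as a block and 8 residual degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes and an adjusted p under 0.05 as the threshold. A moderated F test covered the 3 groups together. The block was chosen because the series design states that all 3 populations came from each biological replicate. The data themselves did not show this pairing. Deviations from the group means correlated between 0.11 and 0.38 in the 5 same-numbered pairs of arrays on 1 slide and between -0.72 and -0.15 in the 10 pairs on different slides. With the slide taken out, 4 of 15 pairs correlated above 0.1. The arrays lay on 2 slides, which were also the 2 scans, and each slide held all 3 populations. Slide 1 held 3 DID+, 3 DID- and 2 CD44DIM arrays, and slide 2 held 2, 2 and 3. In all 5 replicates the DID- and CD44DIM arrays lay on different slides, so each of these pair differences also holds a slide difference. DID+ and DID- shared a slide in replicate 3 only. The main estimates against CD44DIM therefore hold part of the slide difference. Slide was therefore also fitted as a further block, and the groups were also compared within each slide.

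The 31 gene lists, the tests and most alternatives were fixed before the data were examined. They cover lipid metabolism, energy metabolism, cell cycle, epithelial state, stress and signalling, and markers of other cell types that a xenograft could contribute. Each was tested with limma's camera at its preset inter-gene correlation of 0.01, with adjustment over all 93 tests, and again with an estimated correlation and with fry. A list's shift is the median log2 difference of its members minus that of all genes, because the median gene differed between groups by an amount that changed with the scaling. That median was 0.27 between DID+ and DID-, 0.09 between DID+ and CD44DIM and -0.22 between DID- and CD44DIM. With quantile normalisation it was 0.10, 0.03 and -0.09.

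The genes named were set by a rule. CD36 and CD44 were always reported. In each comparison, up to 12 genes with the largest difference in each direction were taken among those past the threshold, with the same sign in all 5 replicate pairs and with an established symbol. In each list, at most the 2 members with the smallest adjusted p in each direction were taken. Where a probe was not well above background on any array of a group, the fold is a lower bound, written as at least N-fold. It sets the brighter group's mean against the mean, per array, of the higher of the dim probe's own value and the lowest value among probes above background.

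The procedure was tested on simulated data for 32013 genes, with 68 genes changed by 1, 66 by 2 and 66 by 4 on the log2 scale in DID+. Without a slide effect, the DID+ against DID- test recovered 13.2% of changes of 1, 39.4% of changes of 2 and 89.4% of changes of 4, with 7 unchanged genes called. With the estimated slide effect added, the replicate block recovered 4.4%, 39.4% and 83.3%, and the replicate and slide blocks together 29.4%, 68.2% and 90.9%. The first run drew noise at the residual SD without slide and the second at that with slide fitted, so the 2 runs are not directly comparable. Noise was drawn independently for each gene, so the false calls do not cover structure shared by genes. Alternatives covered the block, background correction, normalisation, the deposited table, filters, probe choice, slide, weights, variance model and the leaving out of arrays. Fits with slide as a block combined with other changes, slide in place of the replicate number, and gene-by-gene array weights were added after seeing the data. Precision is limited by the number of arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.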

Results

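Gene expression was measured on 15 arrays of 3 cell populations, DID+, DID- and CD44DIM, sorted from xenografts of the human Detroit line. Each population had 5 biological replicates. The series title names CD36, a fatty acid receptor, and stem cells of metastasis as its subject. Levels below are log2 processed signal relative to each array's 75th percentile, given as mean ± SD with n = 5. The 75th percentile of signal ran from 292.3 to 1172, and 57.2% to 88.2% of probes were well above background. DID+ had the lowest cDNA concentration and the lowest signal of the 3 populations in all 5 replicates, with 129.28 to 351.43 ng/ul and 292.3 to 812.7, against 367.46 to 437.73 ng/ul and 777.5 to 1066.4 in DID- and 333.2 to 379 ng/ul and 661.4 to 1172 in CD44DIM. This difference runs with both comparisons of DID+ and cannot be separated from them.

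**Figure D1:**
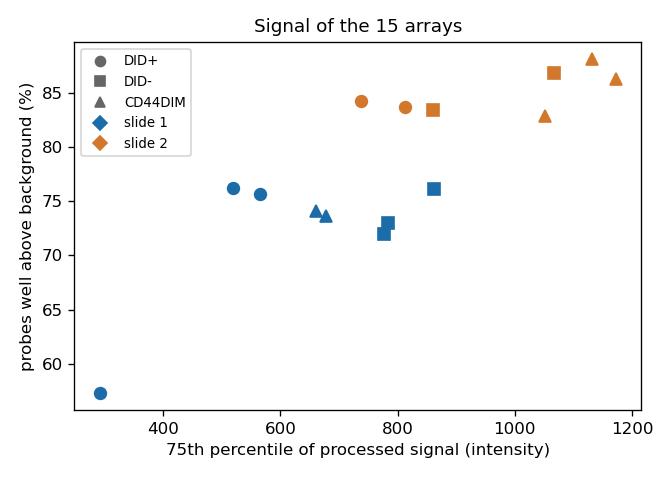
Percent of probes well above background (vertical axis) against the 75th percentile of processed signal (horizontal axis, intensity) for the 15 arrays. Marker shape gives the population and colour the slide. The 7 arrays of slide 2 had 82.9% to 88.2% of probes above background, and those of slide 1 had 57.2% to 76.3%, the lowest being DID+ replicate 3.

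CD44, the surface protein whose dim staining names a sort, was lowest in CD44DIM. Its level was 4.80 ± 0.40 in DID+, 4.41 ± 0.15 in DID- and 3.29 ± 0.32 in CD44DIM (SD, n = 5). It was 2.85-fold higher in DID+ than in CD44DIM (log2 difference 1.51, SE 0.25, adjusted p = 0.0256, higher in 5 of 5 pairs). DID- over CD44DIM gave 2.19-fold with the same probe (SE 0.25 on the log2 scale, adjusted p = 0.0837), which passed the threshold with slide as a block (adjusted p = 0.0142) and lay between 5.34e-05 and 0.52 over 40 alternative settings. This probe lies at chromosome 11, 35253812 to 35253871, on hg19. A second CD44 probe, at 35244791 to 35244850, gave 3.70-fold for DID+ over CD44DIM (adjusted p over probes 0.0219) and 3.72-fold for DID- over CD44DIM (adjusted p over probes 0.0257). CD36 was measured by 1 probe at chromosome 7, 80302711 to 80303343. Its level was -0.69 ± 1.23 in DID+, -1.77 ± 0.33 in DID- and -1.57 ± 0.29 in CD44DIM (SD, n = 5). The difference between DID+ and DID- was 1.09 on the log2 scale (SE 0.44, adjusted p = 0.226, higher in 5 of 5 pairs) and did not pass the threshold. DID+ replicate 3 stood at 1.499 and the other DID+ arrays between -1.42 and -0.97. Without that array the difference was 0.56 (adjusted p = 0.255), and in 40 alternative settings the adjusted p lay between 0.0723 and 0.555. Between DID+ and CD44DIM the CD36 difference was 0.89 (adjusted p = 0.382) and between DID- and CD44DIM it was -0.20 (adjusted p = 0.85).

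**Figure D2:**
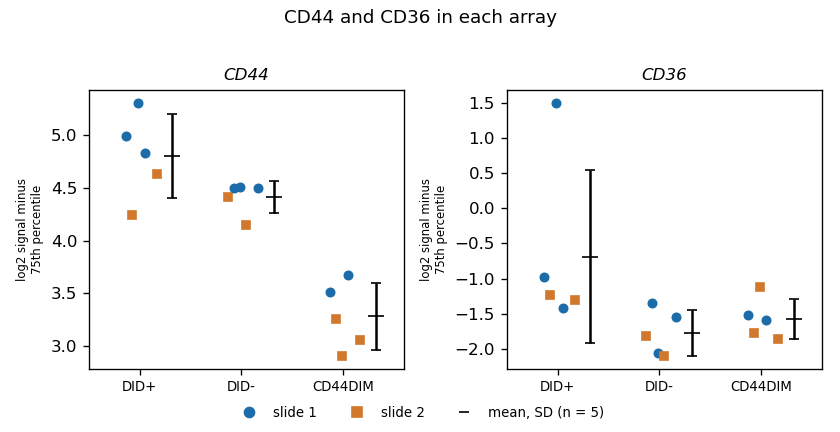
Level of CD44 and of CD36 in each array (log2 signal minus the array's 75th percentile) by population, with colour and shape for slide. Black bars give mean and SD of 5 arrays. CD44 was lowest in CD44DIM at 3.29, and the CD36 mean of DID+ includes 1 array at 1.499.

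RELN, TIE1, S1PR1, NID1, PROX1 and STAB1 had the highest differences between DID+ and DID- among the genes named. RELN, which encodes the secreted glycoprotein reelin, was 125-fold higher in DID+ (log2 difference 6.96, SE 0.85, adjusted p = 0.014), and TIE1, an endothelial receptor kinase, was 105-fold higher (6.72, SE 0.67, adjusted p = 0.00628). S1PR1, a receptor for sphingosine 1-phosphate, was 67.2-fold higher, PROX1, the transcription factor of lymphatic endothelial identity, 41.5-fold, and STAB1, a scavenger receptor, 39.0-fold, each with adjusted p = 0.00628. VIM, the intermediate filament vimentin, was 18.6-fold higher at 3.05 ± 0.35 against -1.16 ± 0.86 (SD, n = 5, adjusted p = 0.00628). NID1, RHOJ, ANXA6, CXCL10, CHST1 and GRAMD1A completed the 12 named genes, with folds from 14.4 to 52.5. In DID- the RELN, TIE1, S1PR1, NID1 and PROX1 probes were well above background on 2 of 5 arrays, as were those of CXCL10 and CHST1, while ANXA6 was on 3 and STAB1 and RHOJ on 4. The lower level of these genes is therefore poorly measured, and their folds and the order of the folds are uncertain. A second CHST1 probe gave a log2 difference of 2.02 against 4.63. The TIE1 probe lies at chromosome 1, 43788328 to 43788387, and the PROX1 probe at chromosome 1, 214184905 to 214184964. Genes lower in DID+ were led by LEFTY1, an inhibitor of Nodal signalling, which was at least 5.24-fold lower (adjusted p = 0.00628). ERCC8 was 5.23-fold lower (adjusted p = 0.0454, well above background on 2 of 5 DID+ arrays), CCND2, a cyclin of the G1 phase, 4.81-fold lower (adjusted p = 0.0454), and CHEK1, a DNA damage checkpoint kinase, 2.53-fold lower (adjusted p = 0.0436).

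In all, 81 genes were higher and 14 lower in DID+ than in DID-, of 32013 tested. With slide as a further block, 5801 were higher and 1356 lower, and without the replicate block 669 were higher and 301 lower. Within slide 1 alone 5377 genes passed and within slide 2 alone 2. The share of higher genes moved with the scaling, from 81 higher and 14 lower to 96 and 47 with quantile normalisation, 250 and 216 with normexp and quantile normalisation and 48 and 17 with scaling to the median. Leaving out 1 array gave between 16 genes (without DID- replicate 2) and 383 (without DID- replicate 4). All 22 genes named from the largest differences had the same sign within both slides and passed with slide as a block. Neither is an independent check, because these genes were chosen for the same sign in every replicate pair of these arrays. The slide block also cannot move their estimates, as DID+ and DID- have equal numbers of arrays on each slide, and it lowered the median residual SD. For 17 of the 22 the fold within slide 1 and that within slide 2 were over 1.5 times apart, RELN with log2 differences of 8.87 and 4.10.

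**Figure D3:**
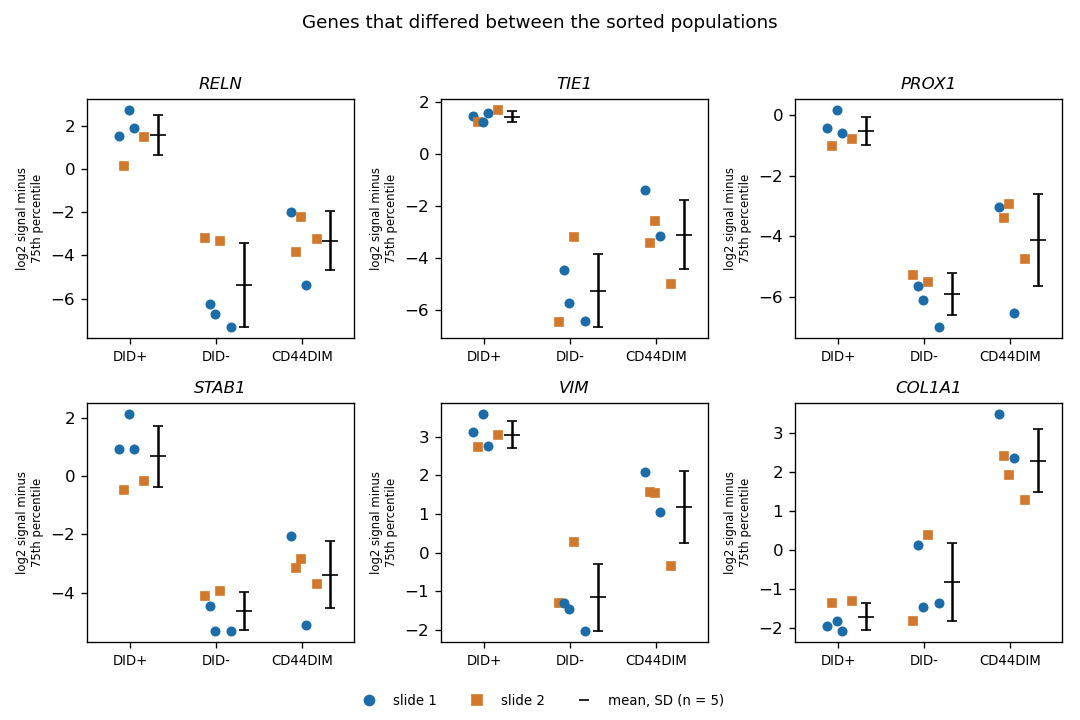
Level of 6 named genes in each array (log2 signal minus the array's 75th percentile) by population, with colour and shape for slide and bars for mean and SD of 5 arrays. RELN, TIE1, PROX1, STAB1 and VIM were highest in DID+, where TIE1 averaged 1.46, and COL1A1 was highest in CD44DIM at 2.29.

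Among the lists fixed beforehand, the endothelial markers rose in DID+ against DID- by 0.61 relative to all genes (camera adjusted p = 7.94e-06). Of 15 members, 2 rose past the threshold over all genes, TIE1 and ROBO4 (5.37-fold, adjusted p = 0.0362), and 8 rose adjusted over the list alone. The call was lost with an estimated correlation (adjusted p = 0.361), and the shift was 0.74 within slide 1 and 0.26 within slide 2. Over all genes, 11 members were higher with slide as a block. Myeloid markers shifted by 0.35 (adjusted p = 0.0564) and fibroblast markers by 0.08 (adjusted p = 0.601), with DPEP1 6.70-fold higher (adjusted p = 0.0415).

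DNA replication genes shifted by -0.76 (adjusted p = 8.99e-10) and mitosis genes by -0.69 (adjusted p = 1.59e-06) in DID+ against DID-. In both lists 0 of 40 members passed over all genes, and 0 adjusted over the list alone. The mean level of the DNA replication list, not set against all genes, was lower in DID+ in every replicate pair. That of the mitosis list was higher in DID+ in replicate 1 (0.656 against 0.521) and replicate 4 (0.597 against 0.46) and lower in the other pairs. Oxidative phosphorylation genes shifted by -0.50 (adjusted p = 1.34e-06, 0 of 43 members, 4 lower adjusted over the list alone). Wnt and Notch targets shifted by -0.47 (adjusted p = 0.00502, 0 of 26 members, 4 lower and 1 higher adjusted over the list alone). Fatty acid beta-oxidation genes shifted by -0.44 (adjusted p = 0.0214, 0 of 31) and cholesterol biosynthesis genes by -0.41 (adjusted p = 0.015, 0 of 25), both with 0 adjusted over the list alone. Mitochondrially encoded genes shifted by 0.33 (adjusted p = 0.00137, 0 of 13, also 0 adjusted over the list alone). All 7 calls were lost with an estimated correlation, where the adjusted p was 0.238, 0.43, 0.596, 0.238, 0.348, 0.669 and 0.635 in this order. With slide as a block, which cannot move these shifts because DID+ and DID- have 3 arrays each on slide 1 and 2 each on slide 2, the members past the threshold over all genes were 12 lower and 2 higher for DNA replication, 7 lower and 1 higher for mitosis, 11 lower for oxidative phosphorylation, 6 lower and 2 higher for Wnt and Notch targets, 4 lower for beta-oxidation, 2 lower for cholesterol biosynthesis and 7 higher for mitochondrially encoded genes. Within slide 1 the shifts were -0.86, -0.91, -0.59, -0.54, -0.41, -0.45 and 0.43 in the same order, and within slide 2 they were -0.58, -0.31, -0.36, -0.35, -0.20, -0.18 and 0.20. The list of fatty acid uptake and binding genes, to which CD36 belongs, did not pass (shift -0.22, adjusted p = 0.388, 0 of 26 members). PFKFB3, which controls glycolytic flux, was 2.79-fold higher in DID+ (adjusted p = 0.0336), and the glycolysis list did not pass (adjusted p = 0.957).

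RELN, TIE1, STAB1 and PROX1 were also higher in DID+ than in CD44DIM, and BPIFB1 and the collagen genes COL1A1 and COL3A1 were lower. RELN was 30.1-fold (log2 difference 4.91, SE 0.85, adjusted p = 0.0317), TIE1 23.6-fold (adjusted p = 0.0183), STAB1 16.5-fold (adjusted p = 0.0158) and PROX1 12.1-fold higher (adjusted p = 0.0192). ITGA9, an integrin subunit, was 8.37-fold and ERG, an endothelial transcription factor, 7.73-fold higher. Small nucleolar RNAs were also among the largest differences, with SNORA23 30-fold higher (4.20 ± 0.36 against -0.71 ± 0.46, SD, n = 5, adjusted p = 0.000109) and SNORD33 7.79-fold higher (adjusted p = 0.0141). SNORA22 was 22.6-fold and RNU4ATAC 8.77-fold higher, but a second probe of each gave a log2 difference of -0.13 and -2.33, so these are uncertain. BPIFB1, a secreted protein of airway and oral mucosa, was 22.2-fold lower in DID+ (adjusted p = 0.00767). COL1A1, a chain of type I collagen, was 16-fold lower (-1.71 ± 0.35 against 2.29 ± 0.81, SD, n = 5, adjusted p = 0.01), and COL3A1 was at least 6.82-fold lower (adjusted p = 0.0414). SULT1E1, an oestrogen sulfotransferase, was 12.9-fold lower (adjusted p = 0.00839), ATP12A, a proton pump, 11.7-fold and CLDN17, a tight junction protein, 10.9-fold lower, both with adjusted p = 0.00767. The probes of RELN and PROX1 were well above background on 4 of 5 CD44DIM arrays and that of SNORA22 on 2, and in DID+ that of BPIFB1 was on 3 and those of SULT1E1 and CLDN17 on 4.

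The comparison gave 154 genes higher and 133 lower in DID+ than in CD44DIM. With slide as a further block 1243 were higher and 781 lower, and without the replicate block 514 were higher and 411 lower. Within slide 1 there were 97 and within slide 2 there were 415. Scaling to the median gave 31 higher and 52 lower. Leaving out 1 array gave between 23 genes (without CD44DIM replicate 6) and 354 (without DID+ replicate 3). All 24 genes named from the largest differences kept their sign within both slides, with folds over 1.5 times apart for 18 of them. They were chosen for the same sign in every replicate pair of these arrays, so the kept sign is not an independent check.

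Lists that rose in DID+ against CD44DIM were led by DNA replication (shift 0.92, adjusted p = 5.02e-15, 7 of 40 members, 26 adjusted over the list alone) and mitosis (shift 0.75, adjusted p = 4.02e-13, 6 of 40, 21 adjusted over the list alone). GINS2 was 2.57-fold and UBE2C 4.01-fold higher (adjusted p = 0.0183 and 0.0129). Cholesterol biosynthesis rose by 0.58 (adjusted p = 5.21e-05), with SQLE, squalene epoxidase, 3.17-fold higher (adjusted p = 0.0359) and 9 members higher and 1 lower adjusted over the list alone. Basal keratinocyte genes rose by 0.385 (adjusted p = 0.00142), with 2 of 26 members past the threshold and 9 adjusted over the list alone. CD44, whose dim staining names the CD44DIM sort, is among the 2, so that member is not independent of the sort. Mitochondrially encoded genes rose by 0.58 (adjusted p = 1.15e-06, 0 of 13 members, 5 adjusted over the list alone), endothelial markers by 0.30 (adjusted p = 0.0071, 2 of 15, 4 adjusted over the list alone) and ribosomal protein genes by 0.19 (adjusted p = 0.00116, 0 of 49 by either adjustment). Ribosomal protein genes turned to -0.11 with slide as a block and quantile normalisation together. Wnt and Notch targets fell (shift -0.34, adjusted p = 0.0283) and so did keratinocyte differentiation genes (shift -0.18, adjusted p = 0.0192), with 0 members of either past the threshold. Adjusted over the list alone, 5 members were lower and 1 higher among the Wnt and Notch targets and 4 were lower among the keratinocyte differentiation genes. All 9 calls were lost with an estimated correlation, where the adjusted p lay between 0.138 (DNA replication) and 0.709 (ribosomal protein genes). The shifts with slide as a block, within slide 1 and within slide 2 were 0.74, 0.61 and 0.78 for DNA replication, 0.57, 0.47 and 0.81 for mitosis, 0.44, 0.44 and 0.47 for cholesterol biosynthesis, and 0.27, 0.13 and 0.42 for basal keratinocyte genes. They were 0.53, 0.37 and 0.67 for mitochondrially encoded genes, 0.308, 0.483 and 0.385 for endothelial markers, and 0.065, 0.017 and 0.178 for ribosomal protein genes. For Wnt and Notch targets they were -0.54, -0.52 and -0.35, and for keratinocyte differentiation genes -0.28, -0.35 and -0.14. Members past the threshold over all genes with slide as a block were 19 higher for DNA replication, 18 for mitosis, 7 for cholesterol biosynthesis, 8 for basal keratinocyte, 7 for mitochondrially encoded, 4 for endothelial and 1 for ribosomal protein genes, 1 higher and 5 lower for Wnt and Notch targets, and 1 higher and 5 lower for keratinocyte differentiation genes. Fibroblast markers shifted by -0.16 (adjusted p = 0.101), with 4 of 16 members lower.

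Between DID- and CD44DIM, CYP4F11, SLC29A1 and the aldo-keto reductase genes AKR1B10 and AKR1B15 were higher in DID-, and THY1, ACTA2 and COL1A1 were higher in CD44DIM. CYP4F11, a fatty acid hydroxylase of the cytochrome P450 family, was 9.51-fold higher in DID- (log2 difference 3.25, SE 0.42, adjusted p = 0.0141). AKR1B10 was 7.10-fold and AKR1B15 6.17-fold higher, both with adjusted p = 0.00626. SLC29A1, a nucleoside transporter, was 7.38-fold higher (2.81 ± 0.10 against -0.07 ± 0.50, SD, n = 5, adjusted p = 0.00626). FANCA and BLM, which act in DNA repair, were 5.58-fold and 5.01-fold higher, and CDK1, the mitotic kinase, 4.62-fold higher (adjusted p = 0.016). Other probes of FANCA and CDK1 did not pass, with log2 differences for FANCA of 1.89 (adjusted p over probes 0.0754) and 1.45 (adjusted p over probes 0.321) against 2.48, and for CDK1 of 1.49 (adjusted p over probes 0.144) against 2.21. A second CYP4F11 probe gave 3.01 (adjusted p over probes 0.0627). In CD44DIM, THY1 was 18.9-fold (adjusted p = 0.0438), ACTA2, smooth muscle actin, 8.71-fold (adjusted p = 0.0266) and COL1A1 8.65-fold higher (adjusted p = 0.0239) than in DID-. ATP12A was 9.85-fold and BPIFB1 9.22-fold higher in CD44DIM (adjusted p = 0.00982 and 0.0182). VIM was 5.08-fold higher in CD44DIM (adjusted p = 0.0427). LRRC17 was 8.65-fold higher in CD44DIM, but a second probe gave a log2 difference of -0.23 in place of -3.11.

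The comparison gave 172 genes higher and 74 lower in DID-, against 611 and 362 with slide as a further block and 486 and 177 without the replicate block. Within slide 1, 0 genes passed by limma, where 3189 had an unadjusted p under 0.05, and within slide 2 there were 408. Leaving out 1 array gave between 6 genes (without DID- replicate 6) and 814 (without DID+ replicate 3). All 24 genes named from the largest differences kept their sign within both slides, with folds over 1.5 times apart for 10 of them. Having been chosen for the same sign in every replicate pair of these arrays, they give no independent check by keeping it. Within slide 1 and slide 2 the log2 difference was -5.51 and -2.91 for THY1 and -3.95 and -2.29 for ACTA2.

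DNA replication genes rose together in DID- against CD44DIM (shift 1.56, adjusted p = 3.65e-46), with 16 of 40 members past the threshold and 31 adjusted over the list alone. This call also held with an estimated correlation (adjusted p = 0.0259), and the shift was 1.42 with slide as a block, 1.45 within slide 1 and 1.38 within slide 2. GINS2 and CDC45, parts of the replicative helicase, were 4.10-fold and 4.37-fold higher (adjusted p = 0.00626 and 0.00982). Mitosis genes rose by 1.44 (adjusted p = 1.52e-42, 10 of 40 members, 32 adjusted over the list alone), with adjusted p = 0.0567 with an estimated correlation. Cholesterol biosynthesis rose by 0.96 (adjusted p = 3e-15, 1 of 25, 10 adjusted over the list alone), basal keratinocyte genes by 0.73 (adjusted p = 6.76e-11, 0 of 26, 4 adjusted over the list alone) and oxidative phosphorylation by 0.59 (adjusted p = 4.12e-12, 0 of 43). The basal keratinocyte list includes CD44, whose dim staining names the CD44DIM sort. Fatty acid and triglyceride synthesis genes passed with a shift of 0.22 relative to all genes (adjusted p = 0.0101), although their own median log2 difference was -0.004 with 14 of 30 members positive, with ACACA, acetyl-CoA carboxylase, 2.05-fold higher (adjusted p = 0.0427), 1 of 30 members past the threshold and 5 adjusted over the list alone. Extracellular matrix and protease genes rose by 0.48 (adjusted p = 0.00502), with 4 members higher and 2 lower of 35, and 7 higher and 4 lower adjusted over the list alone. The higher members included MMP13, a collagenase, and the lower ones COL1A1 and COL1A2. Ribosomal protein genes rose by 0.32 (adjusted p = 0.00571, 0 of 49). Keratinocyte differentiation genes fell in DID- (shift -0.27, adjusted p = 7.18e-06, 0 of 42, 7 lower adjusted over the list alone). Fibroblast markers fell (shift -0.45, adjusted p = 0.00142), with 3 of 16 members lower and 6 adjusted over the list alone, among them COL1A1 and COL1A2 (4.06-fold, adjusted p = 0.0191). Endothelial markers (shift -0.45, adjusted p = 0.0138, 0 of 15 members by either adjustment) and myeloid markers (shift -0.25, adjusted p = 0.0283) also fell, the latter with 1 of 17 members past the threshold, CD74. With an estimated correlation the adjusted p of all these lists other than DNA replication and mitosis lay between 0.109 and 0.709, and these calls were lost. The shifts with slide as a block, within slide 1 and within slide 2 were 1.31, 1.40 and 1.16 for mitosis, 0.81, 0.93 and 0.72 for cholesterol biosynthesis, 0.57, 0.64 and 0.47 for basal keratinocyte genes, and 0.45, 0.46 and 0.40 for oxidative phosphorylation. They were 0.14, 0.24 and 0.10 for fatty acid and triglyceride synthesis, 0.32, 0.43 and 0.19 for extracellular matrix, and 0.23, 0.14 and 0.28 for ribosomal protein genes. For keratinocyte differentiation they were -0.32, -0.34 and -0.27, for fibroblast markers -0.466, -0.545 and -0.413, for endothelial markers -0.26, -0.32 and -0.16, and for myeloid markers -0.19, -0.23 and -0.12. The slide block put these members past the threshold over all genes: 28 higher for DNA replication, 21 for mitosis, 7 for cholesterol biosynthesis, 5 for basal keratinocyte, 4 for fatty acid and triglyceride synthesis and 1 for oxidative phosphorylation genes, 5 higher and 4 lower for extracellular matrix, and 2 lower for keratinocyte differentiation, 4 for fibroblast and 1 for myeloid markers. They were 0 for ribosomal protein genes and endothelial markers.

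**Figure D4:**
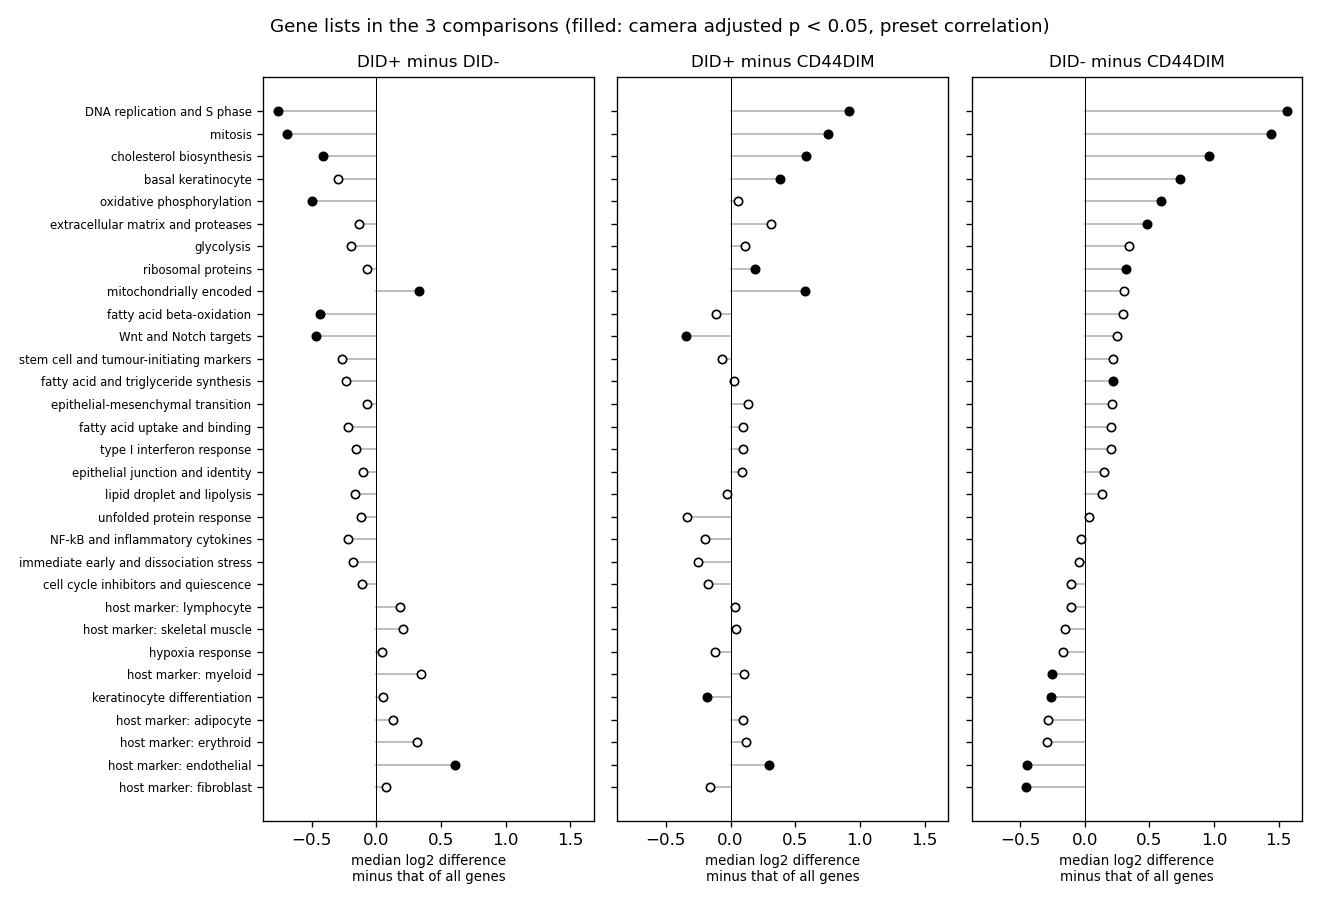
Shift of each of the 31 gene lists (median log2 difference of members minus that of all genes, horizontal axis) in the 3 comparisons. Filled points had a camera adjusted p under 0.05 at the preset correlation. DNA replication had the highest shift in DID- against CD44DIM at 1.56 and the lowest in DID+ against DID- at -0.76.

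Over the 3 populations together, the F test passed 431 genes, and 5421 with slide as a further block. Of the 93 list tests 29 passed, 17 upward and 12 downward, and 1 of these passed with an estimated correlation.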

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

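Tests of the endothelial, fibroblast and slide patterns and the splits within replicates for the F test were chosen after the results were seen, while the other counts over splits of the samples were planned. A value was taken up here when 1 of the 5 arrays of a group stood far from the other 4, which chance alone gives in about 1 in 20 groups. It happened in 17 of 282 groups, and 7 of the 17 were in DID+ replicate 3, the array with the lowest cDNA concentration (129.28 ng/ul) and 57.2% of probes above background.

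In DID+ replicate 3, CD36 stood at 1.499, SNORD33 at 6.263, SULT1E1 at -5.801, SYBU at -5.135 and CD109 at -1.508. Its mean over the fatty acid uptake list was -1.438 and over the lipid droplet list -1.564. CD44DIM replicate 1 had a lipid droplet list mean of -1.488 and SNORA22 at -7.232. DID+ replicate 2 had a quiescence list mean of 0.624. DID- replicate 4 had an epithelial-mesenchymal list mean of -0.134, a fibroblast list mean of -1.623, CD44 at 4.146 and ITGA9 at -1.587. DID- replicate 1 had a ribosomal list mean of 5.883 and CHEK1 at 0.566, and CD44DIM replicate 4 had GRAMD1A at -3.717.

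The 12 named genes higher in DID+ than in DID-, TIE1 and PROX1 among them, kept most of their difference without DID+ replicate 3. Without it, their median log2 difference was 0.95 of that with it, and 9 of the 12 passed the threshold. They had been chosen for 1 sign in all 5 pairs, so a gene resting on 1 array could hardly be among them. These 12 genes therefore cannot tell whether the wider endothelial pattern rests on that array. The fixed endothelial list shifted by 0.26 within slide 2, which does not hold that array, and by 0.74 within slide 1, which does. A smaller share of tumour cells in DID+ could raise markers of whichever other cell types were sorted with them, as far as mouse transcripts bind the human probes, and it stays open. An uneven rise does not exclude it, and host endothelial cells in the sort would be 1 case of it. The endothelial minus fibroblast score was 1.01 higher in DID+ than in DID- (exact permutation p = 0.0625 within the 5 pairs, two-sided, the smallest they can give, and 0.00794 over the 10 arrays without pairs), but all 7 lists of host markers shifted upward, by 0.077 to 0.608, of which 1 passed. Lymphocyte markers, at 0.184, were among the 7, although the mice lack a working adaptive immune system. The score sets the list with the largest of the 7 shifts against that with the smallest. It was chosen after the results were seen, so its p-values are not an independent check. Endothelial cells of the host are a candidate source that also stays open. A further set of 15 endothelial genes did not pass as a set (camera p = 0.399 with an estimated correlation). It left out the fixed list and the genes named from the largest differences, so it cannot exclude this source. Of the 15, 10 lay above the median of all genes. With slide as a block 4 passed upward, FLT4 (1.89) among them, and GNG11 (-2.11) and PDPN (-1.91, also a basal keratinocyte list gene) passed downward. Host endothelial cells and a programme of the tumour cells themselves cannot be told apart here. The probes are for human transcripts and would read RNA of the mouse host only through cross-hybridisation, which was not checked. Of the 15 tested markers of the fixed endothelial list, 13 were above background on all 5 DID- arrays. The sort gates against host cells are not given in the sources used here.

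The higher fibroblast genes of CD44DIM kept their shift with slide as a block (-0.466 for DID- minus CD44DIM). Host fibroblasts in the CD44DIM sort may be a source, but the list missed the threshold with an estimated correlation (adjusted p = 0.191), and sort gates against host cells are again not given. Cross-hybridisation of mouse transcripts to these probes was not checked either. Of the 16 tested members 4 are also in another list. A smaller share of tumour cells in CD44DIM also stays open, as the endothelial minus fibroblast score differed by 0.46 (exact permutation p = 0.125 within the 5 pairs, two-sided, and 0.0556 over the 10 arrays without pairs) and all 7 lists of host markers shifted downward in DID- against CD44DIM, by -0.108 to -0.454, of which 3 passed. A programme of the CD44DIM tumour cells was not tested.

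The rise in the number of genes with slide as a block goes with a signal difference between the 2 slides. The median residual SD was 0.674 without slide and 0.423 with it, and 1 of 100 divisions of the 15 arrays into 8 and 7, the real one, brought it that low, the next being 0.58. DID+ replicate 3 alone does not account for it in DID+ against DID-, where 73 genes passed without that array and 7157 with slide as a block, in DID+ against CD44DIM (354 and 2024) or in the F test (754 and 5421). In DID- against CD44DIM the same 2 counts leave it open, with 814 genes without that array and 973 with slide as a block. With that array left out, however, slide as a block raised the 814 to 3591. This argues against that array alone as the cause of the rise there too.

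The real split is included in each count here. Of 100 splits of the 10 arrays, 3 gave as many genes as the 95 of DID+ against DID- (highest other 7500), 2 as many as the 287 of DID+ against CD44DIM (highest other 10980) and 2 as many as the 246 of DID- against CD44DIM (highest other 11318). Most of these splits break replicate pairs, which the fit keeps. The 16 splits that part all 5 pairs are too few for a share under 0.05. Among them, DID+ against DID- had 1 with as many genes (highest other 0), DID+ against CD44DIM had 1 (highest other 0) and DID- against CD44DIM had 2, the other being the slide split with 11318 genes. For the 431 genes of the F test, 2 of 100 splits that move labels within each replicate gave as many (highest other 6361). Of 100 splits of all 15 arrays, 3 did (highest other 8755). Such shares make chance less likely without excluding it, as arrays of the 2 slides are not interchangeable. The splits that called several times the real number point to a structure of the samples, and the splits with 10980 and 11318 genes separated slide 1 from slide 2 exactly. With slide as a block, DID+ against CD44DIM gave 2024 genes and DID- against CD44DIM 973.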

How the results depend on the processing

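The fits with slide and another change together, slide in place of the replicate number and gene-by-gene array weights were chosen after seeing the data. Counts are given for DID+ against DID- (95), DID+ against CD44DIM (287), DID- against CD44DIM (246) and the F test (431), in this order, and the cause of a change was not tested unless stated. Without the replicate block, which the series design states and the arrays' deviations did not show, they were 970, 925, 663 and 1722. With slide as a further block they were 7157, 2024, 973 and 5421, and all 95, 287 and 246 genes were among them. With slide in place of the replicate number they were 9386, 3540, 1621 and 8437, with slide block and quantile normalisation 3869, 2968, 1135 and 4403, and with slide block and without DID+ replicate 3 8276, 3992, 3591 and 8841. Slide 1 arrays gave 5377, 97, 0 and 2014, and slide 2 arrays 2 and 408 for the comparisons of DID-. Groups compared alone by limma gave 0, 3 and 0 (fewer samples), with 4920 and 3934 genes at an unadjusted p under 0.05 for the counts of 0. Normexp and quantile normalisation gave 466, 1202, 682 and 1550, the deposited values 388, 1103, 639 and 1443, and quantile normalisation 143, 617 and 752, DID- against CD44DIM staying within 1.5 times. Scaling to the median gave 83, 41 and 137 and the trend and robust variance 526, 485 and 770 for the counts other than DID+ against DID-. Probes above background on all arrays (21061 genes tested) gave 294, 500, 496 and 886. The planned array weights did not converge, 1 weight being 1.38e-08, and gave 18808, 2595, 21234 and 22727. Gene-by-gene weights, from 0.0817 to 3.96, gave 20031, 2735, 21811 and 23491, so neither is relied on.

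Leaving out 1 array or 1 replicate gave 0 to 383, 1 to 354, 0 to 814 and 1 to 754 genes, and 25 to 37 of the list tests, against 29. Leaving out any single array moved the counts by over 1.5 times for 14, 13, 14 and 14 of the 15 arrays. Without DID+ replicate 3 they were 73, 354, 814 and 754. With an estimated correlation 1 list test passed, and with fry 20. Of the 70 named results from the largest differences, 0 turned direction where measured in 40 settings (38 were not measured with probes above background on all arrays), and CD36 passed in 0. The 70 were chosen for the same sign in every replicate pair of these arrays, so their kept direction is not an independent check. Many calls were lost, with 2 of the 70 kept when groups were compared alone, 29 with slide 1 arrays, 30 with slide 2 arrays, 50 with scaling to the median, 26 to 67 without 1 array and 1 to 24 without 1 replicate, against 70 without the replicate block or with slide as a further block. Directions turned for RPA2 in DID+ against CD44DIM (0.59 with slide block and without DID+ replicate 3) and for the direction of some list tests. In DID+ against DID- these tests had pointed up without passing, although the shifts were already negative in the main fit. They were -0.20 for glycolysis, -0.10 for epithelial junction and -0.07 for ribosomal proteins. The shift of glycolysis was -0.63 and that of epithelial junction -0.53 with gene-by-gene weights. Epithelial junction was -0.46 with the planned weights, and ribosomal proteins -0.16 with normexp, -0.18 in the deposited table and -0.21 with slide block and quantile normalisation. With the latter, ribosomal proteins, which had passed upward, were -0.11 in DID+ against CD44DIM (adjusted p = 0.538), and epithelial junction was -0.19 in DID- against CD44DIM. Signal over background limits dim probes, since slide 1 arrays had 57.2% to 76.3% of probes above background.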

Other observations

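The test of small nucleolar RNAs was chosen after the results were seen. Several genes of the stress, inflammation and cell cycle inhibitor lists were higher in CD44DIM than in DID-. FOS, an immediate early transcription factor, was 4.09-fold higher in CD44DIM (adjusted p = 0.0284), DDIT3, a transcription factor of the unfolded protein response, 3.37-fold higher (adjusted p = 0.037), and ICAM1, an adhesion molecule, 2.25-fold higher (adjusted p = 0.0284). The cell cycle inhibitor CDKN1C was 2.74-fold higher in CD44DIM (adjusted p = 0.0127). The lists these genes belong to did not pass. The shift was -0.04 for immediate early genes (adjusted p = 0.0546), 0.03 for the unfolded protein response (adjusted p = 0.171, a median above that of all genes although the test pointed down), -0.03 for inflammatory cytokines (adjusted p = 0.332) and -0.10 for cell cycle inhibitors (adjusted p = 0.239). ALDH1A1, an aldehyde dehydrogenase, was 2.73-fold (adjusted p = 0.0162) and KIT 8.60-fold lower (adjusted p = 0.0376, well above background on 2 of 5 DID+ arrays) in DID+ than in CD44DIM, while the list of stem cell markers did not pass (shift -0.07, adjusted p = 0.304). CA12, a carbonic anhydrase, was 4.36-fold higher in DID+ than in CD44DIM (adjusted p = 0.0188), and the hypoxia list did not pass (shift -0.12, adjusted p = 0.964).

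The other lists did not pass in any comparison. In DID- against CD44DIM the shifts were 0.14 for lipid droplet genes, 0.34 for glycolysis, 0.21 for epithelial-mesenchymal transition, 0.15 for epithelial junction, 0.20 for the interferon response, -0.11 for lymphocyte, -0.15 for skeletal muscle, -0.285 for adipocyte and -0.295 for erythroid markers. Of 273 small nucleolar RNAs tested, 9 were higher and 1 lower in DID+ than in CD44DIM, but as a set they did not pass (shift -0.13, adjusted p = 0.898 by limma's camera at the preset correlation). At the preset correlation the set passed in DID+ against DID- (shift -0.30, adjusted p = 0.0258, 3 members higher and 0 lower) and in DID- against CD44DIM (shift 0.26, adjusted p = 0.00405, 1 higher and 0 lower). Both calls were lost with an estimated correlation (adjusted p = 0.182 and 0.143). Adjustment was over the 3 comparisons. Fitted with slide as a block, 38 members were higher and 16 lower in DID+ against DID-, 24 and 6 in DID+ against CD44DIM and 6 and 2 in DID- against CD44DIM.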
